A study of Mus musculus with 18 samples.

How the data were processed

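The series holds RNA sequencing of bone-marrow-derived macrophages from WT, BAFF KO and APRIL KO mice, unstimulated or with 10 ng/ml LPS for 4 h. Per the labels' protocols, RNA was isolated with the mirVana kit and sequenced on a NextSeq 550 as single reads of 85 bp. The labels name the NEBNext Ultra II Directional kit beside the measurement of library concentration and the TruSeq RNA kit for library construction, so whether the libraries keep strand is unclear. Reads were aligned with STAR to mm10, per the submitters' processing notes. The counter, the annotation and any filter on genes are not given in the sources used here.

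The authors deposited 1 table of RPKM values (reads scaled to gene length and to the library's total) for 11164 genes in 18 columns, and columns were matched to samples by the names in the labels. Gene IDs were given symbols from the GENCODE M21 annotation for 11084 IDs, and 80 had none. Because RPKM of few reads are whole multiples of what 1 read is worth, reads could be recovered from the deposited values: 100% came out whole within 0.01 reads, and they summed exactly to the column totals in 18 of 18 columns. The values show that 1 read had been added to each count and that a count of 0 was set to a fixed floor per gene, worth 1 read at a depth of 2636926 reads. Between 259 and 836 genes per column were at this floor, and 1997 genes in at least 1 column. Columns with the lower index number of a library held 1649338 to 1942218 reads in listed genes and those with the higher one 3472495 to 4078562. Of protein-coding genes with 1 exon 0.23% were listed in the table used here, against 63.33% of those with 6 or more, so genes with few exons can hardly be read from it. RPKM is relative to the total of reads, so a few strongly induced genes lower all others.

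The descriptions give 9 library numbers, each with 2 index numbers that differ by 1. The mean RPKM of the 2 columns was taken as 1 library, a choice made before the data were examined, as were the tests, the gene lists and the alternatives not named below as added. Genes with a mean of at least 1 RPKM in at least 1 of the 6 groups were kept (9934). Values were put on the log2(RPKM + 1) scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit on 6 group means, 3 residual degrees of freedom, contrasts, eBayes with a trend; 2-sided), with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The 9 tested comparisons were the LPS response averaged over genotypes and in each genotype, BAFF KO and APRIL KO against WT and against each other under LPS, and the difference of each knockout's LPS response from that of WT. An arm with a lone library is assumed to vary like the other groups. Knockouts without stimulation were compared by size, without a p-value, and genes were counted only where both knockout columns lay beyond both WT columns. Each list's median was set against 10000 random lists of the same size matched on expression.

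The 21 gene lists cover cytokines, chemokines, interferon-stimulated genes, interferon ligands and receptors, guanylate-binding proteins, MHC class I and II, NF-kB feedback, Toll-like receptors, the inflammasome, antimicrobial effectors, alternative activation, prostaglandins, matrix proteases, the BAFF and APRIL axis, glycolysis, cholesterol synthesis, cholesterol efflux, cell cycle, the unfolded protein response and immediate early genes. A further 13 lists hold markers of cell types, RNA quality and sex. Lists were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over 288 list tests. Named genes are the target genes, then per comparison the 12 largest rises and 12 largest falls among called genes whose libraries do not overlap (interactions: adjusted p alone), leaving out genes without a name, then up to 2 rises and 2 falls per list, or the member with the smallest p where none passed. A textbook list of 65 skeletal muscle genes (46 in the table, 38 tested) was written after the pattern was seen.

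Of the 9 comparisons, 3 were tested on simulated data drawn from pooled levels of the real libraries, with 50 genes changed at each fold size. Every gene was given the same spread between libraries, 0.128 on the log2 scale. In the averaged test as many genes were raised as lowered. The false calls below therefore do not cover genes of unequal spread, or falls that come from scaling to the total of reads. In the averaged LPS test 62% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes were recovered with 15 false calls among 9475 genes. For BAFF KO against WT the shares were 12%, 64% and 90% with 4 false calls among 9819 genes, and for the interaction 0%, 8% and 78% with 2 false calls among 9837 genes. No recovered gene had the wrong sign.

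The alternatives were a pseudocount of 0.1, no filter, median ratio scaling, quantile normalization, the 18 columns as separate samples, the lower or the higher index column alone, the replicate number as a block, a fold of at least 2, only the 4 libraries compared, each LPS library left out in turn, and for lists an estimated correlation and fry. Added after seeing the data were limma-voom on the recovered reads and the muscle genes left out. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tnfsf13b was not analysed here, and single genes that are counted in the totals but whose values are not reported here were left out of the text.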

Results

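RNA was measured in macrophages grown from mouse bone marrow, which are the phagocytes that precursors in marrow become in culture. The cells came from wild-type C57BL/6J (WT) mice and from mice lacking BAFF or APRIL. These are related cytokines of the tumour necrosis factor family, best known for keeping B cells and plasma cells alive. Cells were left unstimulated or given 10 ng/ml lipopolysaccharide (LPS), the bacterial cell wall component sensed by Toll-like receptor 4, for 4 h. The series sets BAFF and APRIL against each other in inflammation that leads to preterm birth, and the labels also carry day 16 of gestation. The 18 columns of the table belonged to 9 libraries, each present under 2 neighbouring index numbers. There was 1 unstimulated library per genotype (library 13 for WT, 16 for BAFF KO, 19 for APRIL KO) and 2 LPS libraries per genotype (14 and 15, 17 and 18, 20 and 21). Each library held 5121833 to 6020780 reads in the listed genes; the protocol names about 20 M reads per sample. Columns of 1 library differed a little more than sampling noise (mean chi-square per gene 1.58 to 2.13, where 1 is expected), and columns of different libraries of a group differed more (2.78 to 5.80), and each library was counted as 1 sample. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

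The gene for APRIL, Tnfsf13 (ENSMUSG00000089669, mm10 chromosome 11, 69682846 to 69685784, minus strand), had 0 reads in each of the 6 APRIL KO columns. Those columns held 17077154 reads, which allows up to 0.176 RPM (3 reads over the genotype; intervals and floors here cover counting error only). WT columns had 40.43 RPM of Tnfsf13 and BAFF KO columns 51.6, so WT was at least 230-fold higher than the limit for APRIL KO. By column, WT had 122 and 270 reads unstimulated and 28, 91, 83 and 51 with LPS. BAFF KO had 169 and 317 unstimulated and 56, 113, 67 and 159 with LPS. With LPS, Tnfsf13 fell by 1.48 on the log2 scale in WT (limma, Benjamini-Hochberg adjusted p = 0.00056) and by 1.27 in BAFF KO (adjusted p = 0.0011). The annotation places the read-through gene Tnfsfm13 and the antisense gene Tnfsf13os over the same stretch, and how reads were shared among them is not given. Tnfsfm13, looked up after the data were seen, was read in APRIL KO too, at 46.3 RPKM unstimulated against 65.1 in WT. The gene for BAFF, Tnfsf13b (ENSMUSG00000031497, chromosome 8, 10006467 to 10039072, plus strand), was not analysed here, so the BAFF KO labels were not checked by their target.

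The first comparison asked what LPS did to these cells. LPS raised inflammatory genes in the macrophages of all 3 genotypes. Nos2, the inducible nitric oxide synthase, went from 0.443 ± 0.375 RPKM (SD, n = 3 unstimulated libraries) to 367 ± 89.6 (SD, n = 6 LPS libraries). The cytokine gene Il6 went from 1.38 ± 0.588 to 408 ± 82.4 RPKM, and Cxcl10, which encodes a chemokine induced by interferon, from 31.1 ± 6.41 to 3245 ± 197. Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, went from 1.54 ± 1.47 to 171 ± 68.3 RPKM. Among the genes that fell furthest, Cd300lb, a myeloid activating receptor gene, went from 24.2 ± 2.68 to 1.07 ± 0.512 RPKM, and Cerk, the gene of ceramide kinase, from 40.2 ± 8.87 to 4.01 ± 0.332. On the log2(RPKM + 1) scale, which understates the change of low genes, the averaged changes were 8 for Nos2, 7.43 for Il6, 7.3 for Il1a, 6.97 for Il27, 6.9 for Il1b, 6.88 for Ccl4, 6.67 for Cxcl10, 6.51 for Ccl5, 6.26 for Saa3 and 6.14 for Ptgs2 (adjusted p 3.8e-10 to 2.9e-09). Large falls were -3.64 for Cd300lb, -3.15 for Nfam1, -3.14 for the stress-response gene Sesn1, -3.02 for Cerk and -2.79 for Slc40a1, the iron exporter ferroportin (adjusted p 6.2e-08 to 5e-07).

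The gene lists fixed before the data were examined showed where the response lay. Of 16 proinflammatory cytokines tested, 16 rose, as did 18 of 20 chemokines, 31 of 32 interferon-stimulated genes, 12 of 12 guanylate-binding proteins and immunity-related GTPases, 17 of 17 genes of MHC class I presentation and 23 of 23 genes of NF-kB feedback. Examples were the interferon-stimulated Cmpk2 (5.72) and Rsad2 (5.52), Gbp2 (5.61), whose reads may be shared with its close relatives, the peptide transporter Tap1 (3.05), and the feedback inhibitor Socs3 (4.21). Interferon ligands and receptors had 9 rises and 2 falls of 13 (Irf1 3.64, Ifngr1 -1.27), Toll-like receptor signalling 11 and 4 of 19 (Tlr3 2.48, Tlr13 -1.8), and antimicrobial effectors 13 and 8 of 21 (Saa3 6.26, Hmox1 -1.11). In the list of BAFF and APRIL ligands, receptors and adaptors, 6 of 12 rose and 3 fell, among them the APRIL-binding proteoglycans Sdc4 (3.82) and Sdc1 (-1.49). Cell cycle genes mostly fell, 21 of 24 with 2 rises (Cdc20 -1.85), and cholesterol efflux genes fell in 9 of 9 (Nr1h3, the liver X receptor, -0.94). Adjusted over the list alone, 19 of the 21 lists had the same counts; MHC class II then had 4 rises and 3 falls and the prostaglandin pathway 3 and 8. The limma camera test called 10 lists, all upward, at adjusted p 1.3e-31 for interferon-stimulated genes, 3.1e-21 for NF-kB feedback, 1.6e-16 for chemokines, 5.4e-16 for cytokines, 4.5e-15 for MHC class I and 2.2e-14 for guanylate-binding proteins. Camera was also run with a correlation between genes estimated from the data, which has only 3 residual degrees of freedom. With so few, that setting called 0 of the 21 lists and cannot decide whether a list changed more than other genes. Fry called 18, but it asks only whether members changed at all. Since 7968 of 9934 genes were called here, its calls do not settle the question. None of these camera calls held with an estimated correlation between genes: adjusted p = 0.11 for interferon-stimulated genes and chemokines, adjusted p = 0.19 for guanylate-binding proteins and NF-kB feedback, adjusted p = 0.2 for cytokines and adjusted p = 0.49 for MHC class I. The other 4 camera calls were Toll-like receptor signalling (adjusted p = 3e-04), interferon ligands and receptors (5.1e-05), antimicrobial effectors (9.6e-05) and the BAFF and APRIL list (0.016). With an estimated correlation camera gave these adjusted p = 0.72, 0.49, 0.49 and 0.49, in this order.

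Camera did not call the following lists, whose members went both ways. MHC class II presentation had 4 rises and 4 falls of 13 (Cd40 5.94, H2-DMa -0.69), with a median of -0.03 and a mean of 0.65. The inflammasome list had 5 rises and 6 falls of 14 (Nlrp3 2.73, Txnip -1.69; median -0.15, mean 0.28), alternative activation 7 and 11 of 20 (Il10 5.24, Pparg -2.75; median -0.48, mean 0.05), and the prostaglandin pathway 3 and 9 of 16 (Ptges 3.14, Hpgd -1.47; median -0.35, mean 0.14). Matrix proteases had 6 rises and 8 falls of 20 (Mmp13 4.87, Mmp9 -2.12; median -0.11, mean 0.27), glycolysis 5 and 8 of 17 (Pfkfb3 2.43, Pgam1 -0.83; median -0.12, mean 0.04), cholesterol synthesis 3 and 12 of 19 (Idi1 0.59, Msmo1 -1.22), the unfolded protein response 5 and 9 of 16 (Hspa5 1, Ddit3 -1.97) and immediate early genes 1 and 4 of 7 (Klf6 1.59, Fos -2.63). For the last pair camera pointed up against other genes although their medians were -0.44 and -0.42. Among cell type markers, 9 of 10 neutrophil, 4 of 8 macrophage, 3 of 7 monocyte, 3 of 5 dendritic, 3 of 4 osteoclast, 4 of 4 sex-linked, 1 of 5 B cell and the 1 tested T or NK cell gene fell. There were 3 rises among macrophage, 2 among monocyte, 1 among dendritic and 1 among osteoclast markers, and no call among the mast cell, erythroid, megakaryocyte or stromal markers. After median ratio scaling the falls were 7 neutrophil, 2 macrophage, 3 monocyte, 1 dendritic, 2 osteoclast and 1 sex-linked gene, and there were 2 neutrophil, 4 macrophage, 4 monocyte, 2 dendritic, 1 osteoclast, 1 B cell, 4 mast cell, 4 erythroid, 1 megakaryocyte and 1 stromal gene that rose. Of the 10 mitochondrial and nuclear quality genes 0 were listed.

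In total 7968 of 9934 tested genes passed the averaged test, 1802 higher and 6166 lower with LPS. In single genotypes the counts were 5992 in WT (1356 higher), 5943 in BAFF KO (1590 higher) and 6170 in APRIL KO (1426 higher), and 1101 genes rose and 3024 fell in all 3. The surplus of falls depended on scaling. RPKM as deposited put the median change of all genes at -0.44. Median ratio scaling put it at -0.02, near 0 by construction, with 3084 rises and 2990 falls. Quantile normalization put it at -0.18 with 2418 rises and 4157 falls. In WT, BAFF KO and APRIL KO median ratio scaling gave 2286, 2326 and 2345 rises against 1686, 1723 and 1814 falls. After median ratio scaling the cytokine, chemokine, interferon, guanylate-binding, MHC class I and NF-kB lists kept their 16, 18, 31, 12, 17 and 23 rises, and cell cycle genes still fell in 19 of 24. Glycolysis turned to 10 rises and 2 falls, cholesterol synthesis to 7 and 5, MHC class II to 7 and 0, the inflammasome to 8 and 4, matrix proteases to 8 and 4, alternative activation to 9 and 8, the unfolded protein response to 7 and 4 and immediate early genes to 3 and 1. Cholesterol efflux kept 5 of its 9 falls, with 2 rises. Ccl6, the 1 chemokine that fell (-0.41, adjusted p = 0.00026), was at 0.1 (adjusted p = 0.15) after median ratio scaling.

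The next comparison set BAFF KO against WT under LPS. BAFF KO macrophages made far less interleukin-1 message. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, minus strand) reached 371 ± 3.25 RPKM (SD, n = 2) in BAFF KO against 2395 ± 137 (SD, n = 2) in WT, and its neighbour Il1a 189.5 ± 19.6 against 651 ± 38.2. Mmp13, a collagenase gene, was at 126 ± 3.08 against 525 ± 3.16 RPKM, Plaur, the urokinase receptor gene, at 110.3 ± 5.97 against 342 ± 8.07, and Ccl7, a monocyte chemoattractant gene, at 72.2 ± 2.07 against 237 ± 14.3. The metallothionein gene Mt2 was at 42.9 ± 3.47 against 464 ± 43.5 RPKM (the reads of Mt2 may be shared with its close relative Mt1). Other genes were higher in BAFF KO: Cxcl9, an interferon-induced chemokine gene, at 132 ± 1.27 against 38 ± 1.82, Il12b, the shared subunit of interleukins 12 and 23, at 149 ± 7.22 against 51.7 ± 0.233, and Mertk, a receptor for apoptotic cells, at 51 ± 4.97 against 13.9 ± 1.34 RPKM.

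**Figure D1:**
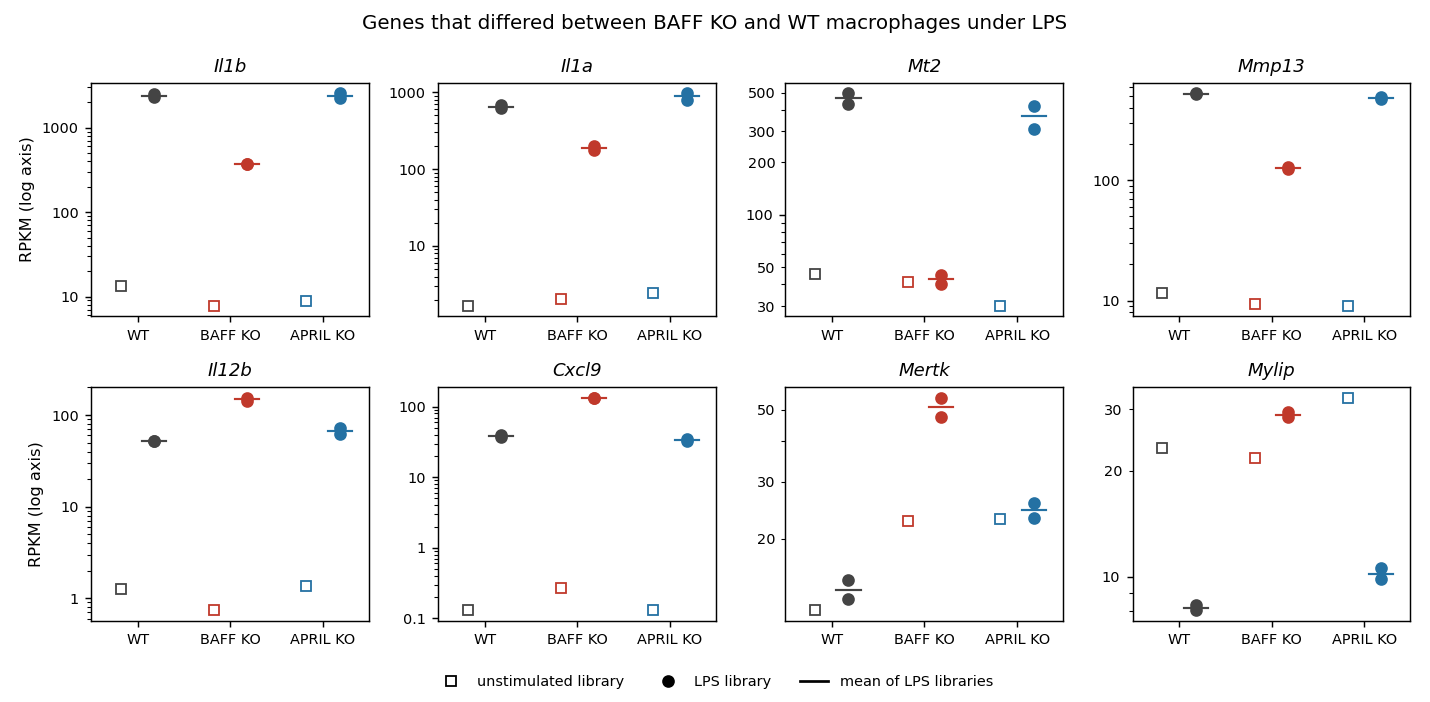
RPKM of 8 genes on a log axis in each of the 9 libraries, by genotype; open squares are unstimulated libraries, filled circles LPS libraries and lines the mean of the 2 LPS libraries. Il1b under LPS was at 369 and 373 RPKM in BAFF KO against 2298 and 2492 in WT and 2269 and 2549 in APRIL KO, while Cxcl9 was at 131 and 133 against 36.7 and 39.3 in WT and 33.1 and 35.3 in APRIL KO; unstimulated Cxcl9 had 0 reads in WT and APRIL KO and is drawn at its floor of 0.131.

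On the log2 scale, large falls outside muscle genes included Mt2 -3.4, the uncharacterised U90926 -3.31, the EGF receptor inhibitor gene Errfi1 -2.8, Il1b -2.69, Il19 -2.42 and Mmp13 -2.05 (adjusted p 2.4e-05 to 0.00088). Large rises included Mertk 1.8, Cxcl9 1.77, the cell cycle kinase gene Wee1 1.71, Mylip, an E3 ligase for the LDL receptor, 1.71, the monoamine oxidase gene Maoa 1.64 and Il12b 1.51 (adjusted p 0.00028 to 0.0025). In contrast, several LPS-induced genes, chosen after their values were seen, gave no call: Tnf was at 708 ± 9.07 RPKM in BAFF KO and 648 ± 35.9 in WT (0.13, adjusted p = 0.44), Nos2 at 0.05 (adjusted p = 0.85), Cxcl10 at -0.14 (adjusted p = 0.33) and Il6 at -0.53 (adjusted p = 0.065). In total 828 genes differed, 396 higher and 432 lower in BAFF KO, of which 49 and 124 by at least 2-fold. Without library 14, 15, 17 or 18 the test called 310, 331, 226 and 215 genes, and the shallower column of each library alone gave 229. Treating the 18 columns as separate samples gave 2706. Of 68 named and called genes 35 stayed called whichever LPS library was left out, among them Il1b, Il1a, Mmp13, Plaur, Ccl7, Mt2, U90926, Errfi1, Il19, Cxcl9, Il12b, Mertk, Wee1, Mylip and Maoa.

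By list, 8 of 20 chemokines were lower in BAFF KO and 1 higher (Ccl7 -1.7, Cxcl3 -1.61, Cxcl9 1.77); adjusted over the list alone 10 were lower and 2 higher. Camera gave adjusted p = 1.2e-05 for the chemokines, and adjusted p = 0.2 with an estimated correlation. Guanylate-binding proteins had 3 of 12 higher (Gbp7 0.61, Gbp9 0.5, relatives that may share reads), 7 adjusted over the list alone (camera 0.00025; adjusted p = 0.49 with an estimated correlation). In the unfolded protein response 3 of 16 were lower (Xbp1 -0.62, Atf4 -0.47), 10 adjusted over the list alone (camera 0.00025; adjusted p = 0.26 with an estimated correlation). MHC class II had 5 of 13 lower (H2-Aa -1.38, H2-Ab1 -1.31), also 5 adjusted over the list alone (0.00082; adjusted p = 0.78 with an estimated correlation). NF-kB feedback had 7 of 23 lower and 2 higher by either adjustment, with Ier3 at -1.2 (0.0064; adjusted p = 0.58 with an estimated correlation). Immediate early genes had 1 of 7 lower (Fos -1.07), 5 adjusted over the list alone (0.0077; adjusted p = 0.72), and glycolysis 1 of 17 (the glucose transporter Slc2a1 -1) by either adjustment (0.028; adjusted p = 0.58). Left out singly, libraries 14, 15, 17 and 18 each ended the calls of Gbp7, Gbp9, Xbp1 and Atf4; 14, 15 and 17 that of Fos; 15, 17 and 18 that of H2-Ab1; 18 that of H2-Aa; and 20 and 21 that of Gbp7.

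Camera called none of the other 14 lists. Proinflammatory cytokines split into 2 higher (Il12b 1.51, Il12a 1.16) and 4 lower (Il1b -2.69, Il1a -1.78) of 16, or 4 and 7 adjusted over the list alone. Alternative activation had 4 higher and 5 lower of 20 (Mertk 1.8, the interleukin-4 receptor gene Il4ra -1.57, the scavenger receptor gene Msr1 -1.27), with a median of 0.19 and a mean of -0.01, and antimicrobial effectors 3 and 4 of 21 (the oxidase subunit gene Ncf1 0.64, the zinc transporter gene Slc39a14 -1.68, Saa3 -1.3), with a median of 0.11 and a mean of -0.09. Adjusted over the list alone these had 6 and 6, and 4 and 6. The prostaglandin pathway had 3 of 16 lower by either adjustment (the phospholipase gene Pla2g4a -1.09), with a median of 0.02 and a mean of -0.11, and the BAFF and APRIL list 3 of 12 lower (Sdc4 -1.1, Sdc1 -1.03), joined by 2 higher adjusted over the list alone. Interferon-stimulated genes had 3 of 32 higher, or 4 with 1 lower adjusted over the list alone. Cholesterol efflux genes had 3 of 9 higher, or 3 with 1 lower adjusted over the list alone. Il12a was no longer called without library 14, 17 or 18.

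**Figure D2:**
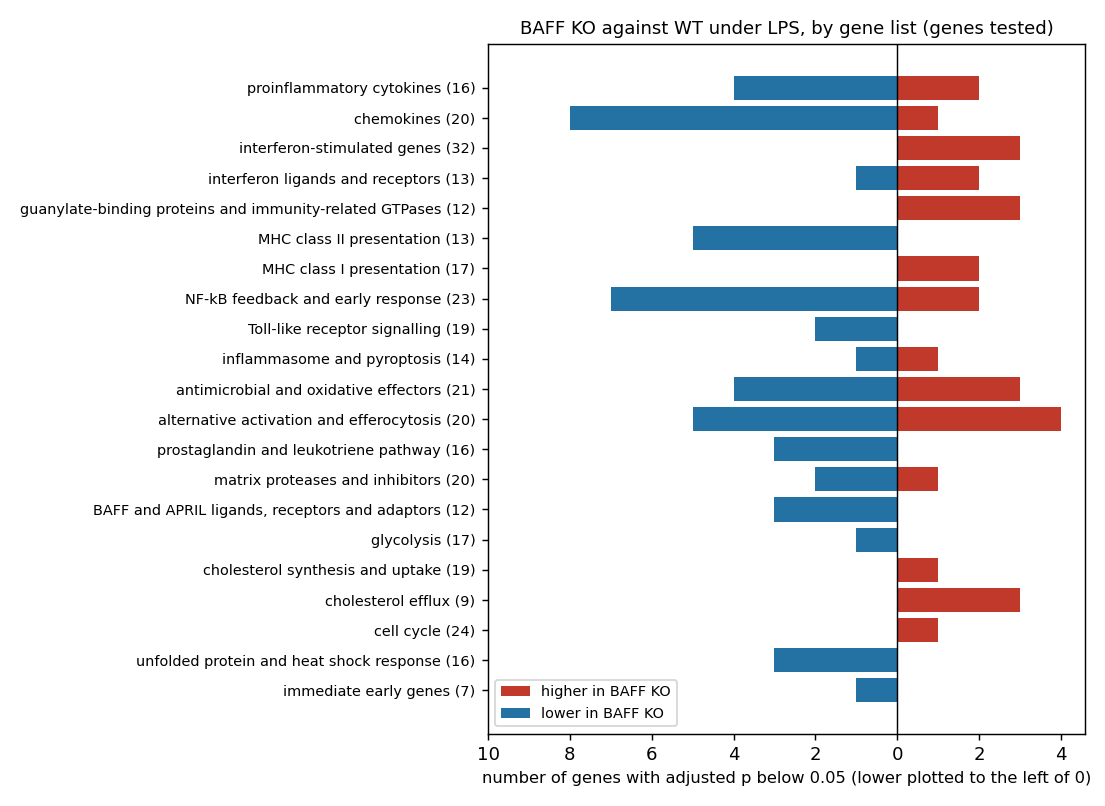
Number of genes per list with a Benjamini-Hochberg adjusted p below 0.05 for BAFF KO against WT under LPS; bars to the right of 0 count genes higher in BAFF KO, bars to the left genes lower, and the number tested stands in parentheses. Chemokines had 8 lower and 1 higher, NF-kB feedback 7 and 2, and MHC class II 5 and 0.

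Markers of other cells moved with these differences. Neutrophil markers were higher in BAFF KO for 6 of 10 genes (8 adjusted over the list alone), including, picked after their values were seen, the granule protein genes Elane (1.1) and Mpo (1.12, not called without library 18), and none was lower; camera gave adjusted p = 6e-05, and adjusted p = 0.49 with an estimated correlation. Monocyte markers had 3 of 7 higher and osteoclast markers 2 of 4, macrophage markers 1 higher and 2 lower of 8, and B cell markers 1 of 5 lower (camera 0.014; adjusted p = 0.65 with an estimated correlation). Skeletal muscle genes were the other group. Tnnc2, the gene of fast troponin C, was at 36.9 ± 15.2 RPKM in WT, 2.85 ± 0.433 in BAFF KO and 3.37 ± 1.2 in APRIL KO under LPS, and Acta1, skeletal actin, at 40.2 ± 10.6, 5.26 ± 0.35 and 6.12 ± 2.29. Of 38 tested genes in a textbook muscle list, written only after this was seen, 34 were lower in BAFF KO than in WT (median -1.75). With the muscle genes left out, 776 genes still differed between BAFF KO and WT. Stromal markers varied between single libraries without a call.

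**Figure D3:**
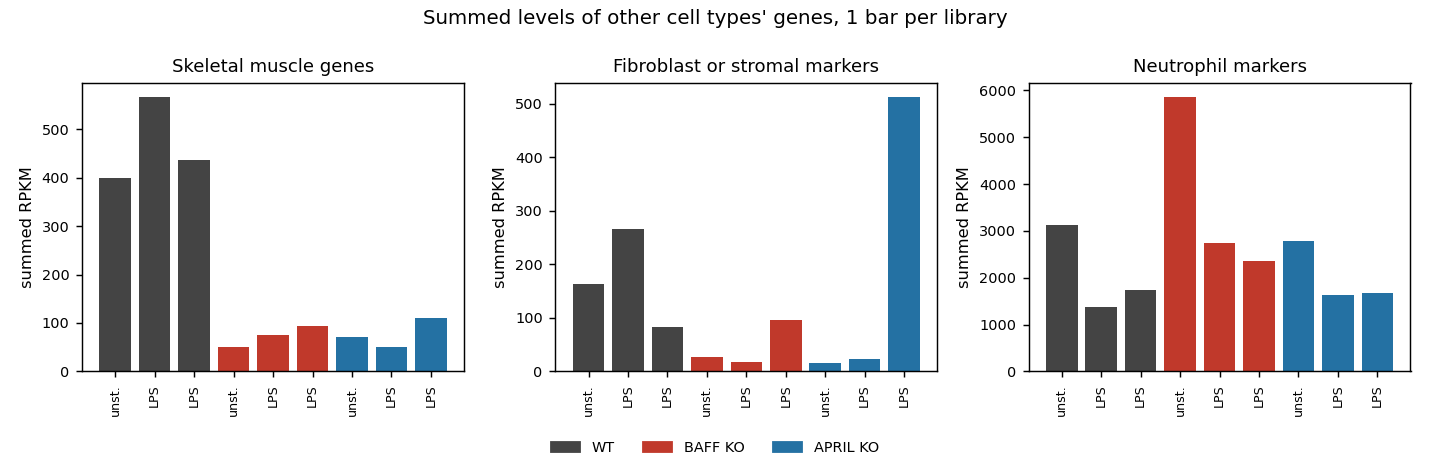
Summed RPKM of 38 skeletal muscle genes, stromal markers and neutrophil markers in each library, 1 bar per library from 0. Muscle genes summed to 400.1, 568 and 436 in the WT libraries and to between 50.5 and 111 in the knockouts; stromal markers reached 513 in 1 APRIL KO library with LPS; neutrophil markers were at 5869 in unstimulated BAFF KO against 3128 in WT.

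The matching comparison of APRIL KO with WT under LPS gave a different picture. Apart from Tnfsf13 itself (-3.69, adjusted p = 0.00019, a fitted value that depends on the floor), nearly all genes that fell were those of skeletal muscle: Tnnc2 -3.08, the myosin light chain gene Myl1 -2.93, Acta1 -2.55, the calcium pump gene Atp2a1 -2.53 and the intermediate filament gene Des -2.42 (adjusted p 0.015 to 0.029). Inflammatory genes gave no call. Il1b was at 2409 ± 198 RPKM in APRIL KO (SD, n = 2) and Mmp13 at 483 ± 10.5, and in each list but that of BAFF and APRIL, where Tnfsf13 was called, the member with the smallest p stayed above the threshold, such as Il1a (0.43, adjusted p = 0.21), Nos2 (0.59, adjusted p = 0.15), Mertk (0.77, adjusted p = 0.065) and Gbp7 (0.75, adjusted p = 0.1). In total 21 genes differed, 20 lower and 1 higher; 18 of the falls were in the muscle list, and the other 2 were Tnfsf13 and the muscle phosphofructokinase gene Pfkm (-1.27). The 1 rise, Gm8995 (1.09), and Pfkm were looked up after their values were seen. Without the muscle genes 1 call was left, Tnfsf13. Tnnc2, Acta1 and Des were not called without library 14, 17, 18 or 20, Myl1 also without 15 and Atp2a1 also without 21; Gm8995 and Pfkm were not called without any 1 of the LPS libraries.

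Camera called the guanylate-binding proteins upward in APRIL KO (adjusted p = 0.00052; adjusted p = 0.49 with an estimated correlation), with 0 of 12 members called over all genes and 2 adjusted over the list alone. It called matrix proteases downward (0.035; adjusted p = 0.83 with an estimated correlation), with 0 of 20 called by either adjustment. Mast cell markers (0.0094; adjusted p = 0.49 with an estimated correlation) and erythroid markers (0.02; adjusted p = 0.74 with an estimated correlation) were higher as lists with no gene called over all genes, and 2 erythroid genes adjusted over the list alone. Beyond these, adjusted over the list alone, the inflammasome had 2 rises, and antimicrobial effectors and alternative activation 2 rises and 1 fall each. Toll-like receptors and MHC class I had 1 rise each, as did the list of interferon ligands and receptors, by the receptor gene Ifnar1 (0.41). The prostaglandin pathway had 1 change each way. The count was fragile: 2, 1, 1 and 2 genes were called without library 14, 17, 18 or 20, 1 when only the 4 libraries compared were fitted, 0 from the shallower columns by limma (1142 genes had an unadjusted p under 0.05 there and 1539 in the full test), and 84 by limma-voom on recovered reads, a tool added after seeing the data. Of these 84 genes 52 were higher and 32 lower, and 18 columns as separate samples gave 757 higher and 604 lower, so the balance of 1 higher and 20 lower was not kept.

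Both knockouts were set against the same WT libraries, which gives shared values by chance. In both knockouts 19 genes fell, where independent lists would share 0.87, and 1 rose (0.04 expected); unchanged groups simulated against these controls shared 0.16. Across genes, which are not independent replicates, the changes correlated at r = 0.54 against 0.5 simulated. They had a covariance of 0.0587 against 0.0157. The 19 shared falls were 18 genes of the muscle list and Pfkm, and the shared rise was Gm8995. All 38 tested muscle genes were higher in each WT library than in each knockout library. The shared falls therefore show no change beyond the muscle pattern. Without the muscle genes r was 0.48, no higher than simulated, and the covariance 0.0454, still above the simulated value. The 2 WT libraries cannot be split into groups of 2, so part of the excess may come from the shared controls.

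The knockouts were then compared directly with each other under LPS. Il1b and Il1a were lower in BAFF KO than in APRIL KO by log2 changes of -2.69 and -2.21, U90926 by -3.22, Mt2 by -3.05, the semaphorin gene Sema4c by -2.34 and Mmp13 by -1.93 (adjusted p 2.3e-05 to 0.00061). Ptgs2 was at 97 ± 4.71 RPKM in BAFF KO (SD, n = 2) and 247 ± 15.8 in APRIL KO (-1.34, adjusted p = 0.0011). Tnfsf13, the gene lost in APRIL KO (4.18), Maoa (2.14), Cxcl9 (1.91) and the glutathione transferase gene Gsta3 (1.71) were higher in BAFF KO, as were Irf1, an interferon-response transcription factor gene (1.06), and Il12b (1.15). The test called 550 genes, 246 higher and 304 lower in BAFF KO, and 402 of them also differed from WT in the same direction, 169 higher and 233 lower. Both comparisons use the same BAFF KO libraries: unchanged groups simulated with them shared 0.26 genes, and independent lists of these lengths would share 9.81 higher and 13.22 lower, so part of the excess may come from the shared libraries. Without library 17, 18, 20 or 21 the count was 96, 157, 148 and 145; voom called 837. Of the 38 muscle genes 0 were called by limma between the knockouts.

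By list, chemokines had 9 of 20 lower and 1 higher in BAFF KO than in APRIL KO, 10 and 3 adjusted over the list alone (camera 0.0011; adjusted p = 0.34 with an estimated correlation). NF-kB feedback had 8 of 23 lower and 1 higher, 8 and 2 adjusted over the list alone (0.00045; adjusted p = 0.49), and the unfolded protein response 2 of 16 lower (Chac1 -0.98), 7 adjusted over the list alone (2.1e-05; adjusted p = 0.2 with an estimated correlation); Chac1 was not called without library 17, 18, 20 or 21. MHC class II had 5 of 13 lower, 6 with 1 higher adjusted over the list alone (0.011; adjusted p = 0.83), MHC class I 1 of 17 higher (H2-Q6 0.85, not called without library 17 or 21, whose reads may be shared with its relatives), 4 adjusted over the list alone (0.0021; adjusted p = 0.83), and immediate early genes 1 of 7 lower, 2 adjusted over the list alone (0.0076; adjusted p = 0.72 with an estimated correlation). Matrix proteases had a median of 0.01 and a mean of -0.18, and the BAFF and APRIL list -0.12 and 0.1. Neutrophil markers were again higher, 6 of 10 with 1 lower (0.00011; adjusted p = 0.49 with an estimated correlation), and lower lists were B cell markers (0.0061; adjusted p = 0.58), dendritic markers (0.022; adjusted p = 0.49) and erythroid markers (0.04; adjusted p = 0.78 with an estimated correlation).

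Whether the response to LPS itself differed was tested as an interaction. The response of BAFF KO minus that of WT, on the log2 scale, was -1.97 ± 0.15 (SE) for Il1b (adjusted p = 0.0052), -1.98 for Il1a, -1.77 for Mmp13, -3.25 for Mt2 and -3.31 for U90926. The response was more positive in BAFF KO for Il12b (1.88), Cxcl9 (1.6), Mylip (1.8) and Irf1 (0.94; adjusted p 0.0046 to 0.036 over these genes). Unstimulated U90926 had 0 reads in all 3 genotypes and Cxcl9 in WT and APRIL KO, so these values depend on the floor, and for Cxcl9 voom gave -0.46 (adjusted p = 0.9). In total 44 genes had a different response, 22 each way, a balance that was not kept by voom (444 higher, 155 lower) or with 18 columns as separate samples (1454 and 739). Lists by camera were chemokines (downward, 0.0024; adjusted p = 0.38 with an estimated correlation; 1 called each way, 7 lower and 2 higher adjusted over the list alone) and guanylate-binding proteins (upward, 0.0022; adjusted p = 0.5; 0 called, 4 adjusted over the list alone). Antimicrobial effectors were called too (downward, 0.04; adjusted p = 0.72; 0 called, 9 lower and 3 higher adjusted over the list alone), as was glycolysis (downward, 0.03; adjusted p = 0.58; 0 called, 1 lower adjusted over the list alone). The remaining calls were MHC class I (downward, 0.03; adjusted p = 0.83; 0 by either adjustment) and neutrophil markers (downward, 0.031; adjusted p = 0.72 with an estimated correlation; 0 called, 2 lower adjusted over the list alone). The count rests on few libraries, since each unstimulated arm is 1 library: without library 14, 15, 17, 18, 20 or 21 it was 16, 7, 0, 3, 19 and 19, with 2141 genes at an unadjusted p under 0.05 in the full test, 2084 without library 17, and 599 called by voom. None of the 28 named genes kept its call in every case; Il1b and Mt2 were not called without 17 or 18, and Mmp13 and U90926 not without 17.

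For APRIL KO the test of a different LPS response called 0 genes by limma and 0 by limma-voom, with 337 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.67, for Ptgs2 (1.54). Camera called guanylate-binding proteins upward (0.00082; adjusted p = 0.49 with an estimated correlation), interferon-stimulated genes upward (0.018; adjusted p = 0.56), MHC class I downward (0.014; adjusted p = 0.83) and stromal markers upward (0.031; adjusted p = 0.83 with an estimated correlation), each with 0 members called by either adjustment. The last moved with library 21, where the collagen gene Col1a1, looked up after the data were seen, was at 253 RPKM against 5.65 in library 20. The single unstimulated libraries added to this difference, as stromal markers there summed to 16.1 RPKM in APRIL KO and 163 in WT. The 2 interaction contrasts share the WT libraries. They correlated at r = 0.38 across genes against 0.5 simulated, with a covariance of 0.0587 against 0.0473.

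Before stimulation there was 1 library per genotype, so differences have no replicate check and no p-value. Genes were counted if they differed from WT by at least 1 on the log2(RPKM + 1) scale and both knockout columns lay beyond both WT columns. In the BAFF KO library these were 180 of 9934 genes, 48 higher and 132 lower, and in APRIL KO 130, 15 higher and 115 lower. With a pseudocount of 0.1 these counts were 464 (130 higher, 334 lower) and 335 (103 higher, 232 lower). Higher in both was Marco, a scavenger receptor gene of macrophages, at 86.4 RPKM in BAFF KO and 91.1 in APRIL KO against 24.7 in WT. Higher in BAFF KO were Maoa (36.3 against 11), the iron exporter gene Slc40a1 (45.6 against 15.5), Gsta3 (31.5 against 9.5) and the neutrophil protease gene Elane (24.6 against 8.26). Lower in both were muscle and matrix genes: Thbs4 was at 19.8 RPKM in WT and had 0 reads in either knockout, Dcn, the gene of decorin, was at 20.1 in WT against 0.338 in BAFF KO and 0.767 in APRIL KO, and Col3a1 at 36 against 3.2 and 1.28. Among the lists, stromal markers had a median of -2.93 in BAFF KO and -3.31 in APRIL KO, both at percentile 0 of 10000 random lists matched on expression. The random lists draw genes singly, so lists whose members move together reach extreme percentiles more easily. These percentiles are not p-values. In BAFF KO neutrophil markers were at 0.99, mast cell markers at 0.51, monocyte markers at 0.49 and MHC class I at 0.37 (each at percentile 100). NF-kB feedback was at -0.27 and immediate early genes at -0.62 (both percentile 0), and MHC class II at -0.37 and B cell markers at -0.73 (both percentile 0.1). In APRIL KO mast cell markers were at 0.4 (percentile 99.9), erythroid markers at 0.29 (99.5), osteoclast markers at -0.54 (0.1) and the unfolded protein response at -0.21 (0.3). The cytokine medians were -0.06 in BAFF KO (percentile 36.9) and 0 in APRIL KO (percentile 58.1).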

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

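The simulated overlaps and the tests of a weaker stimulation, of fewer macrophages and of neighbouring genes were chosen only after the difference between BAFF KO and WT had been seen; the count of other splits was fixed before.

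The responses to LPS of BAFF KO and WT were set against each other by an interaction test, which called 44 genes; 40 of them also differed between BAFF KO and WT under LPS and 35 between BAFF KO and APRIL KO. These tests share libraries: unchanged groups shared 0.22 and 0.14 genes in simulation, independent lists would share 0.88 higher and 0.96 lower, and 0.54 higher and 0.67 lower, and part of the excess over these values may come from the shared libraries, as the overlap was not split by library. The count rests on single libraries: without library 14, 15, 17 or 18 the test called 16, 7, 0 (2084 at an unadjusted p under 0.05) and 3 genes, without 20 or 21 it called 19, and of the 28 named genes 0 kept their call in all 6 cases. In 34 of the 44 the unstimulated BAFF KO library lay on the other side of WT and so added to the difference, and each unstimulated value is 1 library. Several inflammatory genes rose less in BAFF KO. Il1b rose by 5.4 on the log2 scale in BAFF KO, 7.37 in WT and 7.93 in APRIL KO (difference BAFF KO minus WT -1.97), and Il1a by 5.95, 7.93 and 8.01 (-1.98). Under LPS Il1b differed by -2.69, more than its response did, so it was already lower in the unstimulated BAFF KO library than in WT. For Il1a the difference under LPS, -1.78, was smaller than that of the response. Mmp13 rose by 3.62, 5.39 and 5.59 (-1.77), and Plaur by 1, 2.4 and 2.43 (-1.4). The fitted LPS changes in BAFF KO of the metallothionein gene Mt2 (0.06; difference -3.25), of Sema4c (0.03; -2.41) and of Il19 (0.31; -2.34) were near 0, where WT had 3.31, 2.44 and 2.65. U90926 (-3.31), the transcription regulator gene Id1 (-2.45), the heme synthesis gene Alas1 (-2.03), Timd4 (-1.95), Tarm1 (-1.9), Mt1 (-1.89), Ccl4 (-1.3) and Msr1 (-1.11) also had lower values.

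The response was more positive in BAFF KO for Wee1 (2.29), Il12b (1.88), Mylip (1.8), Atp6v0c (1.66, with processed copies that share its reads), Cxcl9 (1.6, but -0.46 with adjusted p = 0.9 by limma-voom), Cited2 (1.55), Tut4 (1.47), Itga4 (1.46), Slc6a6 (1.45), Osbpl8 (1.39) and Irf1 (0.94). Unstimulated WT had 0 reads of Cxcl9, and why limma-voom differed there was not tested. The fitted change of Mylip was -1.41 in WT and -1.57 in APRIL KO and 0.4 in BAFF KO. Irf1 rose by 4.3 in BAFF KO, 3.36 in WT and 3.28 in APRIL KO. The response of WT and that of APRIL KO were not shown to differ for any gene by limma (0 called, 337 at an unadjusted p under 0.05, and 0 by limma-voom).

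A weaker stimulation of the BAFF KO cultures would lower the response of nearly all genes. Of 358 genes that rose at least 4-fold in APRIL KO, 48% rose less in BAFF KO than in WT, which argues against it for genes that rose; of 163 that fell at least 4-fold, 74.2% fell less, and the median difference of 0.33 (0.08 over all genes) leaves it open for those. Fewer macrophages in the culture would lower macrophage markers along with Il1b, but their median was -0.09 (SD 0.85, 8 markers) against -2.69 for Il1b. This argues only against a loss of macrophages as large as the fall of Il1b. A smaller shift in the mix of cells was not tested and stays open. Neutrophil markers summed to 2736 and 2358 RPKM in the BAFF KO libraries with LPS, against 1382 and 1740 in WT. Genes carried along near the targeted locus would be called more often than others. Within 10 Mb of Tnfsf13b 5 of 52 tested genes were called, against 823 of 9882 elsewhere (odds ratio 1.17, 95% interval 0.36 to 2.94, Fisher's exact test, 2-sided p = 0.619). An enrichment up to the upper end of this interval is not excluded. With only 52 tested genes there, most of the 828 calls had to lie elsewhere, whatever the cause. Effects of a neighbouring variant on distant genes were not tested. The loss of BAFF itself stays open as a candidate explanation, since Tnfsf13b was not analysed here and genotype, culture and library preparation may go together.

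Against the averaged LPS response of 7968 genes, other choices of the unstimulated library within each genotype gave at most 0 genes. Of the 27 splits 1, the real one, was as large. This share of 0.037 is the smallest that 27 splits allow, so chance is argued against but not excluded. Every other split mixed LPS and unstimulated libraries within a group, which widens the spread and lowers its count.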

How the results depend on the processing

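Limma-voom on recovered reads and the removal of muscle genes were chosen only after the data were seen. The LPS response stayed within 1.5 times of its counts when libraries were left out (averaged 7750 to 7805, WT 5173 to 5842, BAFF KO 5050 to 5854, APRIL KO 5309 to 6145). Leaving out 1 LPS library gave 215 to 584 genes for BAFF KO against WT, 1 to 24 for APRIL KO against WT, 96 to 418 between the knockouts, and 0 to 19 and 0 to 1 for the different responses of BAFF KO and APRIL KO (0 by limma with 2084 and 340 genes at an unadjusted p under 0.05 without library 17 and 15). Where the library belongs to the comparison fewer libraries were left, but the count also depended on which library it was. The cause of these changes was not tested.

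A fold of at least 2 left 2374 genes in the averaged response, 2530 in WT, 2484 in BAFF KO, 2712 in APRIL KO, 173 for BAFF KO against WT and 130 between the knockouts, by construction. Median ratio scaling called 3972 in WT and put Ccl6 at 0.1 where it had been -0.41 in the averaged response, while quantile normalization called 70 different responses of BAFF KO. Taking 18 columns as separate samples gave 2706 for BAFF KO against WT, 1361 for APRIL KO against WT, 1824 between the knockouts, and 2193 and 8 different responses, since it counts each library 2 times. The lower index column alone gave 229, 0 (1142 at an unadjusted p under 0.05), 164, 2 and 1. With no filter APRIL KO differed from WT in 5 genes and the response of BAFF KO in 15. Only 4 libraries gave 1 gene for APRIL KO, by construction fewer samples, and leaving out muscle genes also 1. Limma-voom called 84 for APRIL KO, 837 between the knockouts and 599 different responses of BAFF KO, with Cxcl9 at -0.46. A pseudocount of 0.1 raised the unstimulated counts to 464 in BAFF KO and 335 in APRIL KO, where low genes count more. Gene lists had 79 calls by camera, of which 0 held with an estimated correlation. The estimate rests on 3 residual degrees of freedom, so that setting cannot decide whether a list changed more than other genes. Fry called 96, but it asks only whether members changed at all. Where no cause is given, the cause was not tested.

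The replicate number as a block gave 15 different responses of BAFF KO, and changed no other count by over 1.5 times. Deviations of libraries with the same number correlated at -0.18, -0.1 and 0.12, so the numbers were not taken to pair the libraries. Of single named genes, a call was lost in 383 and kept in 1147 of 1530 cases without 1 library. It was lost for 86 with the lower and 21 with the higher index column, 54 at a fold of 2, 41 with no filter, 32 with the block (1 gained), 22 with only the 4 libraries, 10 with voom (12 gained), 9 after median ratio scaling (2 gained), 5 after quantile normalization (2 gained) and 4 with a pseudocount of 0.1 (3 gained). With 18 columns 42 were gained, and 1 without muscle genes. Depth limits the lowest genes, since 1997 genes were at the floor in at least 1 column; whether it is behind the calls lost in the shallower columns was not tested.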

Other observations

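The genes of metals, iron and the X end, and the tests of muscle RNA and of scaling, were chosen only after the values were seen.

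Some genes known to handle metals or heme, picked singly after their values were seen and not tested as a group, differed between BAFF KO and WT under LPS. Beside the metallothionein genes Mt2 (-3.4) and Mt1 (-1.52, limma adjusted p = 0.00053), which may share reads, the heme synthesis gene Alas1 was at 32.9 ± 0.771 RPKM in BAFF KO (SD, n = 2) against 85 ± 10.1 in WT and 90.3 ± 5.75 in APRIL KO (-1.34 against WT, adjusted p = 0.00075). The zinc and iron importer gene Slc39a14 was lower (-1.68, adjusted p = 0.0043), and so was Hamp, the gene of the iron hormone hepcidin, at 3.6 ± 0.875 RPKM against 9.88 ± 2.65 in WT (-1.23, adjusted p = 0.015, not called without library 14, 17 or 18). The iron exporter gene Slc40a1 was higher, at 5.16 ± 0.202 RPKM against 1.49 ± 0.126 (1.31, adjusted p = 0.0019). Hmox1, which breaks down heme, was at 235 ± 1.24 RPKM against 172 ± 1.52 (0.44, adjusted p = 0.012, not called without library 14, 15, 17 or 18). Before stimulation it was at 699 RPKM in BAFF KO, 305 in WT and 322 in APRIL KO.

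A few other immune genes, also picked after their values were seen, differed as well. Il1rn, the gene of the interleukin-1 receptor antagonist, was at 244 ± 9.21 RPKM in BAFF KO (SD, n = 2) against 439.9 ± 44.4 in WT (-0.85, limma adjusted p = 0.0027), in the direction of Il1a and Il1b. Timd4, a receptor for apoptotic cells, was at 0.302 ± 0.0627 against 4.46 ± 0.101 RPKM (-2.07, adjusted p = 0.00053). Spp1, the gene of osteopontin, was at 1889 ± 175 against 1006 ± 269 RPKM (0.93, adjusted p = 0.03, not called without library 14, 17 or 18). Marco was at 52.9 and 69.1 RPKM in the WT LPS libraries, 143 and 97 in BAFF KO (0.95, adjusted p = 0.031, not called without library 14, 15 or 17) and 182 and 146 in APRIL KO (1.41, adjusted p = 0.053).

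Single genes stood apart by genotype. Gm21887, at the end of the X chromosome (mm10 170009659 to 170019281), was at 152, 119 and 104 RPKM in the WT libraries, 11.7, 4.96 and 4.35 in BAFF KO and 41.6, 34.7 and 53.9 in APRIL KO. Its neighbour Mid1 was at 6.69 and 6.86 RPKM in WT under LPS, 1.63 and 1.56 in BAFF KO and 4.98 and 7.65 in APRIL KO (BAFF KO against WT -1.58, limma adjusted p = 0.0043). Cers4, on the chromosome of Tnfsf13b and within 10 Mb of it (chromosome 8, 4493026 to 4531680), was at 4.55, 2.11 and 1.91 RPKM in BAFF KO. In WT it was at 0.406, 0.335 and 0.466 (BAFF KO against WT under LPS 1.1, limma adjusted p = 0.0048). The Y-linked genes Ddx3y and Eif2s3y were read in all 9 libraries, at 12.9 to 26.5 and 30.6 to 50.4 RPKM, although the labels carry a day of gestation.

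Muscle genes were high in the WT libraries, with and without LPS. Of 46 listed genes of the textbook list, taken without a filter on level, 44 (95.7%) were higher in each of 3 WT libraries than in each of 6 knockout libraries, as were all 20 tested ones not called in APRIL KO against WT, so muscle RNA in the WT libraries is a candidate explanation, found and tested on the same data. Among the abundant ones Acta1 was at 33.1, 47.7 and 32.7 RPKM in WT and Tnnt3 at 45.2, 66.7 and 43.9, and 0 of the genes were in another list. A scaling factor per library would move all genes alike and is argued against, since the median log2 difference of WT minus APRIL KO under LPS lay 1.95 above that of all genes (SD of all genes 0.29). Genotype stays open, because the summed level of the lowest WT library was 3.6 times that of the highest knockout library and genotype and muscle RNA go together in these libraries.

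More genes fell than rose with LPS. The 823 genes that rose at least 2-fold went from 4.9% to 26.7% of reads, which lowers the share left to all others by a log2 change of -0.38, against a median of -0.44 over all genes, so scaling to the total of reads may account for most of the surplus. After median ratio scaling 2990 genes fell and 3084 rose, but that scaling brings the median change near 0 by construction. These counts therefore cannot tell whether more genes fell per cell. Since no added RNA of known amount was analysed here, such falls cannot be told apart from scaling.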
